A study of Mus musculus with 70 samples.

How the data were processed

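Per the submitters' processing notes, reads were handled with bcl2fastq 2.19, Trimmomatic 0.35, HISAT2 2.1.0, Cufflinks, SAMtools 1.8 and HTSeq 0.11.2 on mm10, with no order or role given for each. Per the labels, total RNA was extracted with miRNeasy and DNase, depleted of ribosomal RNA and made into Illumina TruSeq Stranded Total RNA libraries with 12 cycles of amplification. The gene annotation and strand setting of the counting are not stated. The deposited counts, 1 table with 24439 rows, were used as they were, except that 16 rows repeating a gene with identical counts were dropped, leaving 24423.

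The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Each time was fitted alone with its 4 groups (24, 24 and 22 libraries) by edgeR quasi-likelihood after filterByExpr and TMM scaling, which left 12558, 12647 and 12826 genes. Comparisons over times used 1 model of 12 groups and 70 libraries (13252 genes). P values were adjusted by Benjamini and Hochberg over the genes of each comparison. Standard errors are the absolute log2 fold change over the square root of F, an approximation. Normalised CPM used the TMM factors of all 70 libraries.

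Gene lists, 36 in number and 33 with at least 3 tested members, were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over lists. Calls per list are those of the whole comparison, and the counts adjusted over the list alone use the members only. Genotype calls near Slc26a4 were tested by Fisher's exact test on gene midpoints, with positions for 99.9% of tested genes. The likeness of wildtype and knockout effects was measured by Pearson and Spearman correlation across genes, with a standard error by leaving out 1 library at a time.

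The rule for named genes was Slc26a4 in each comparison, and per silica comparison the 10 largest increases and 5 largest decreases among genes past adjusted p 0.05 with a mean of at least 1 CPM. From each list it took up to 4 members past the threshold, or 2 values where none passed. Per genotype, interaction and time comparison it took the 10 smallest adjusted p in each direction, or the 3 smallest p where none passed. Chil3, Clca1, Retnla, Gpnmb in single mice, Vnn1 and Slc13a3 outside 9 months, Mir6236, and the genes near Slc26a4 were named outside that rule. Some genes that the rule took are not reported here.

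The groups, comparisons, lists, named-gene rule and alternatives were chosen before the data were examined, except the setting without 3 air mice of 9 months, the chromosome 12 window, the reading of list directions and the tests of explanations. Alternatives were DESeq2 size factors in edgeR, the DESeq2 Wald test, no low-count filter, a mean CPM of 1, all 70 libraries, the compared groups only, voom quality weights, 1 surrogate variable and each library left out. In a self-test 200 genes were changed in simulated counts of the same size, and in wildtype mice at 1 day 62.7%, 95.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 10 false among 182 calls. A raised list was found with an adjusted p of 2.36e-39, with 1 of 32 other lists called.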

Results

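Slc26a4, the targeted gene, encodes the anion exchanger pendrin and lies on chromosome 12 at 31519814 to 31560055 of mm10 (GRCm38). Its transcript rose with silica in wildtype lungs, from 8.46 ± 3.62 to 48.0 ± 16.6 normalised CPM (counts scaled to a common library total, mean ± SD, 6 mice each) at 1 day and from 11.7 ± 2.18 to 57.6 ± 13.7 at 3 months (log2 fold changes of 2.62 and 2.29, standard errors 0.25 and 0.22). Knockout lungs held less, 1.74 ± 0.851 in air and 12.8 ± 5.67 after silica at 1 day, and 2.13 ± 0.888 and 16.0 ± 11.0 at 3 months. Knockout reads at this locus also rose with silica, by a log2 fold change of 2.88 (standard error 0.45, adjusted p = 8.00e-05) at 1 day and 2.66 (0.40, adjusted p = 4.47e-05) at 3 months.

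Each mouse gave these normalised CPM of Slc26a4, sorted from low to high. In wildtype mice at 1 day the values were 4.22, 5.11, 6.93, 9.51, 12.4 and 12.6 in air and 24.8, 34.9, 44.2, 56.6, 58.2 and 69.6 after silica. For knockout mice of 1 day the values were 0.982, 1.08, 1.24, 1.91, 2.02 and 3.24 in air and 6.01, 6.44, 13.5, 14.2, 16.3 and 20.5 after silica. In wildtype mice at 3 months the values were 9.07, 10.0, 10.9, 12.0, 13.3 and 15.0 in air and 43.0, 45.2, 50.5, 59.8, 73.4 and 73.8 after silica. For knockout mice of 3 months the values were 1.06, 1.41, 1.55, 2.77, 2.93 and 3.08 in air and 3.38, 11.4, 13.8, 14, 17.2 and 36.4 after silica. In wildtype mice at 9 months the values were 6.42, 10.3, 16.8, 21.6 and 74.2 in air and 20.5, 52.4, 55.8, 66.9 and 79.1 after silica. For knockout mice of 9 months the values were 1.32, 2.67, 2.96, 3.71, 16.8 and 51.7 in air and 10.3, 11.1, 12.4, 12.7, 13.5 and 13.8 after silica. Every knockout mouse lay below every wildtype mouse of the same exposure and time, except in air at 9 months. There 1 wildtype mouse reached 74.2 and 1 knockout mouse (KO_air_9m replicate 4) 51.7, which was above all other knockout mice of any time (at most 36.4) and within the range of wildtype silica mice of 9 months, against its label. Its genotype was not tested in another way. With these mice in, the group means were 25.9 ± 27.6 for 5 wildtype and 13.2 ± 19.7 for 6 knockout mice. After silica at 9 months they were 54.9 ± 21.9 for 5 wildtype and 12.3 ± 1.37 for 6 knockout mice.

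The data were lung RNA counts from 70 male mice of strain 129S-Slc26a4tm1Erg/AjgJ, exposed at about 3 months of age for 6 hours a day on 4 days to filtered air or to 15 mg/m3 crystalline silica. Lungs were taken 1 day, 3 months or 9 months later, with 6 mice in each of 10 groups and 5 in each of the 2 wildtype groups of 9 months. Libraries held 802478 to 5596318 counts. Of all counts 8.33% fell on Lars2, from a source not tested. Values in brackets after a gene are log2 fold changes with their standard errors, and each passed an adjusted p under 0.05 in edgeR unless a larger adjusted p is printed.

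**Figure D1:**
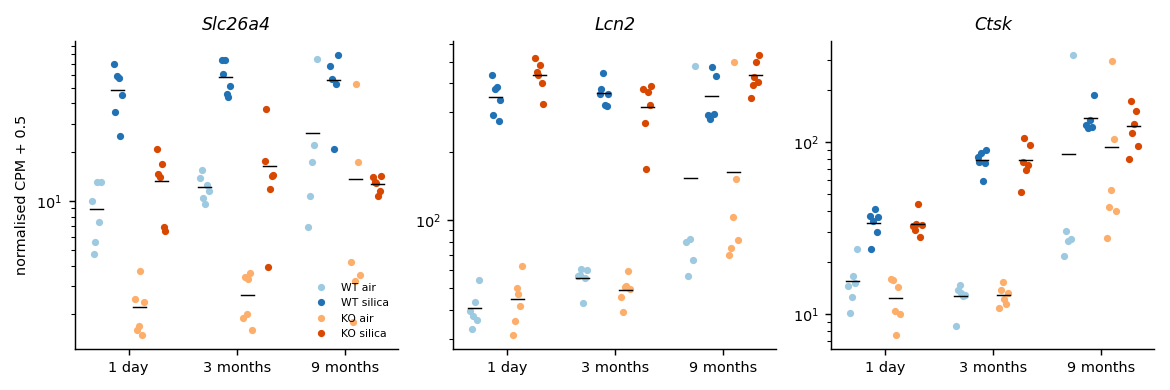
Normalised CPM of Slc26a4, Lcn2 and Ctsk in each mouse (points) and group means (bars) by time, genotype and exposure. 0.5 was added for the log scale, and groups hold 6 mice except the wildtype groups of 9 months with 5.

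Silica raised inflammatory secretory genes at 1 day in wildtype lungs. The acute phase genes Saa3 (4.80 ± 0.33) and Lcn2 (3.14 ± 0.14) rose, Saa3 from 1.64 ± 0.892 to 41.7 ± 13.5 CPM and Lcn2 from 40.4 ± 7.5 to 350 ± 61.3 CPM (6 against 6 mice). With them rose the neutrophil chemoattractants Cxcl3 (4.84 ± 0.59), Cxcl5 (4.28 ± 0.62) and Cxcl1 (3.70 ± 0.27) and the growth factor Csf2 (1.74 ± 0.27). The chemokines Ccl3 (2.97 ± 0.40), Ccl22 (1.8 ± 0.24), Ccl9 (1.61 ± 0.20) and Ccl6 (1.38 ± 0.10), which draw monocytes and lymphocytes, rose as well. Dividing-cell genes rose too, with Mki67 (1.98 ± 0.25), Top2a (1.56 ± 0.24), Birc5 (2.15 ± 0.42) and Kif11 (1.58 ± 0.32).

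Macrophage genes that rose included the osteoclast-type protease Ctsk (1.22 ± 0.17), the lipid-laden macrophage genes Spp1 (0.98 ± 0.12), Gpnmb (0.91 ± 0.13) and Mmp12 (1.86 ± 0.37), the scavenger receptor Marco (1.13 ± 0.15) and the chitinase-like Chil1 (2.69 ± 0.14). The epithelial immunoglobulin carrier Pigr (2.13 ± 0.12), the surfactant collectin Sftpd (0.69 ± 0.08), the metalloreductase Steap4 (1.90 ± 0.18) and the cystine carrier Slc7a11 (1.76 ± 0.24) rose. Others were the surface antigen Ly6i (4.71 ± 0.45), the costimulatory receptor Tnfrsf9 (3.87 ± 0.49), the complement genes Cfb (1.61 ± 0.14) and C3 (0.90 ± 0.10), the interleukin 1 antagonist Il1rn (1.68 ± 0.24) and the interferon-stimulated Ifit1 (1.17 ± 0.20) and Ifit3 (0.77 ± 0.13). The strongest falls were in Acaa1b (-1.34 ± 0.37), Sphkap (-1.25 ± 0.29), Cidec (-1.14 ± 0.22), Hspb7 (-1.11 ± 0.24) and Mb (-1.07 ± 0.27), genes of peroxisomes, fat droplets and muscle. Smooth muscle Myh11 (-0.31 ± 0.06) and club cell Cyp2f2 (-0.37 ± 0.07) also fell.

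At 1 day in wildtype mice 298 of 12558 tested genes passed adjusted p under 0.05 in edgeR, 245 higher and 53 lower, and 105 of them changed at least 2-fold. With voom quality weights the count was 761, with the compared groups only 641, with all 70 libraries 220 and without KO_silica_1d replicate 3, which shares the model, 528 (348 higher, 180 lower). Of 33 fixed gene lists tested by camera 20 passed, and 12 of these with an estimated correlation. Of 9 acute phase genes 7 rose and 2 did not pass (8 higher over the list alone, median 0.72, adjusted p = 1.48e-42, adjusted p = 4.51e-06 with an estimated correlation). Of 5 neutrophil chemoattractants 4 rose and 1 did not pass (4 higher over the list alone, median 3.70, adjusted p = 1.76e-21, adjusted p = 2.14e-05 with an estimated correlation). Of 6 CC chemokines 5 rose and 1 did not pass (5 higher over the list alone, median 1.71, adjusted p = 1.25e-26, adjusted p = 4.51e-06 with an estimated correlation). Of 11 proliferation genes 7 rose and 4 did not pass (11 higher over the list alone, median 1.51, adjusted p = 3.57e-17, adjusted p = 0.00511 with an estimated correlation). Of 13 recruited macrophage markers 6 rose and 7 did not pass (7 higher and 1 lower over the list alone, median 0.37, adjusted p = 2.86e-11, adjusted p = 0.00123 with an estimated correlation). Of 12 complement genes 2 rose and 10 did not pass (3 higher over the list alone, median 0.23, adjusted p = 2.16e-08, adjusted p = 0.0211 with an estimated correlation). Of 10 inflammasome genes 4 rose and 6 did not pass (6 higher over the list alone, median 0.71, adjusted p = 4.23e-07, adjusted p = 0.0202 with an estimated correlation). Of 15 interferon-stimulated genes 3 rose and 12 did not pass (11 higher over the list alone, median 0.73, adjusted p = 4.42e-10, adjusted p = 0.0235 with an estimated correlation). Of 18 oxidative stress genes 5 rose and 13 did not pass (7 higher over the list alone, median 0.22, adjusted p = 5.39e-07, adjusted p = 0.00529 with an estimated correlation). Of 6 neutrophil markers 2 rose and 4 did not pass (5 higher over the list alone, median 0.62, adjusted p = 1.97e-05, adjusted p = 0.0282 with an estimated correlation). The heart muscle list of the pulmonary vein had a median of -0.65 (adjusted p = 1.17e-05 by camera, adjusted p = 0.167 with an estimated correlation, adjusted p = 0.0693 by fry) with 0 of 10 members past the threshold in edgeR, and 8 lower when adjusted over the list alone.

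Knockout lungs also raised inflammatory secretory genes at 1 day. Saa3 (5.88 ± 0.39) and Lcn2 (3.35 ± 0.15) rose, Saa3 from 0.854 ± 0.619 to 55.8 ± 21.5 CPM and Lcn2 from 44.3 ± 11.3 to 435 ± 66.5 CPM (6 against 6 mice). The neutrophil chemoattractants Cxcl3 (5.56 ± 0.66), Cxcl5 (5.27 ± 0.72) and Cxcl1 (4.82 ± 0.34) and Csf2 (1.8 ± 0.27) rose, as did the chemokines Ccl3 (3.14 ± 0.47), Ccl17 (3.01 ± 0.47), Ccl22 (2.12 ± 0.29), Ccl9 (1.81 ± 0.21) and Ccl6 (1.32 ± 0.10). Dividing-cell genes rose with Cdk1 (2.46 ± 0.43), Mki67 (1.83 ± 0.26), Top2a (1.70 ± 0.27) and Rrm2 (1.70 ± 0.31).

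Other knockout increases at 1 day were the macrophage genes Marco (1.86 ± 0.17), Ctsk (1.37 ± 0.19), Spp1 (0.96 ± 0.13), Gpnmb (0.94 ± 0.14) and Fabp5 (0.61 ± 0.11), the epithelial genes Pigr (2.16 ± 0.14) and Sftpd (0.96 ± 0.09), the metalloreductase Steap4 (2.25 ± 0.20) and the cystine carrier Slc7a11 (1.41 ± 0.26). The antigen Ly6i (3.89 ± 0.43), the receptor Tnfrsf9 (3.72 ± 0.58), the macrophage secretory gene Wfdc17 (2.95 ± 0.44) and the matrix genes Timp1 (1.36 ± 0.35) and Fn1 (0.31 ± 0.08) rose. So did the complement genes Cfb (1.54 ± 0.14) and C3 (1.02 ± 0.10) and Il1rn (1.55 ± 0.26). Falls were smaller and included the calcium-binding Cpne5 (-1.06 ± 0.29), the tight junction gene Cldn8 (-1.02 ± 0.25), the repair gene Ercc8 (-0.94 ± 0.20) and the lipid desaturase Scd1 (-0.63 ± 0.14).

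In knockout mice at 1 day 242 of 12558 tested genes passed adjusted p under 0.05 in edgeR, 214 higher and 28 lower, with 91 changed at least 2-fold. With the compared groups only the count was 122, with all 70 libraries 184, with 1 surrogate variable 363 and it was 282 without KO_silica_1d replicate 3. That mouse stood apart, since its chi-square against each other mouse of its group was 13.6 to 15.6 per degree of freedom, against 1.65 to 3.77 between the others, and its voom quality weight was 0.192. Of 33 lists 19 passed, and 11 of these with an estimated correlation. Of 9 knockout acute phase genes 6 rose and 3 did not pass (7 higher over the list alone, median 0.75, adjusted p = 3.30e-52, adjusted p = 1.19e-06 with an estimated correlation). Of 5 knockout neutrophil chemoattractants 4 rose and 1 did not pass (4 higher over the list alone, median 4.82, adjusted p = 5.47e-25, adjusted p = 4.07e-06 with an estimated correlation). Of 6 knockout CC chemokines 5 rose and 1 did not pass (5 higher over the list alone, median 1.97, adjusted p = 2.10e-25, adjusted p = 3.15e-06 with an estimated correlation). Of 11 knockout proliferation genes 7 rose and 4 did not pass (10 higher over the list alone, median 1.48, adjusted p = 4.76e-22, adjusted p = 0.00128 with an estimated correlation). Of 13 knockout recruited macrophage markers 7 rose and 6 did not pass (8 higher over the list alone, median 0.61, adjusted p = 1.04e-14, adjusted p = 1.74e-04 with an estimated correlation). Of 12 knockout complement genes 5 rose and 7 did not pass (8 higher over the list alone, median 0.58, adjusted p = 9.25e-14, adjusted p = 0.00306 with an estimated correlation). Of 10 knockout inflammasome genes 3 rose and 7 did not pass (6 higher over the list alone, median 0.73, adjusted p = 8.03e-07, adjusted p = 0.0144 with an estimated correlation). Of 15 knockout interferon-stimulated genes 3 rose and 12 did not pass (8 higher over the list alone, median 0.33, adjusted p = 4.17e-07, adjusted p = 0.0535 with an estimated correlation). Of 18 knockout oxidative stress genes 3 rose and 15 did not pass (6 higher over the list alone, median 0.18, adjusted p = 3.17e-05, adjusted p = 0.0131 with an estimated correlation). Of 6 knockout neutrophil markers 6 did not pass (2 higher over the list alone, median 0.43, adjusted p = 0.0179, adjusted p = 0.198 with an estimated correlation).

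**Figure D2:**
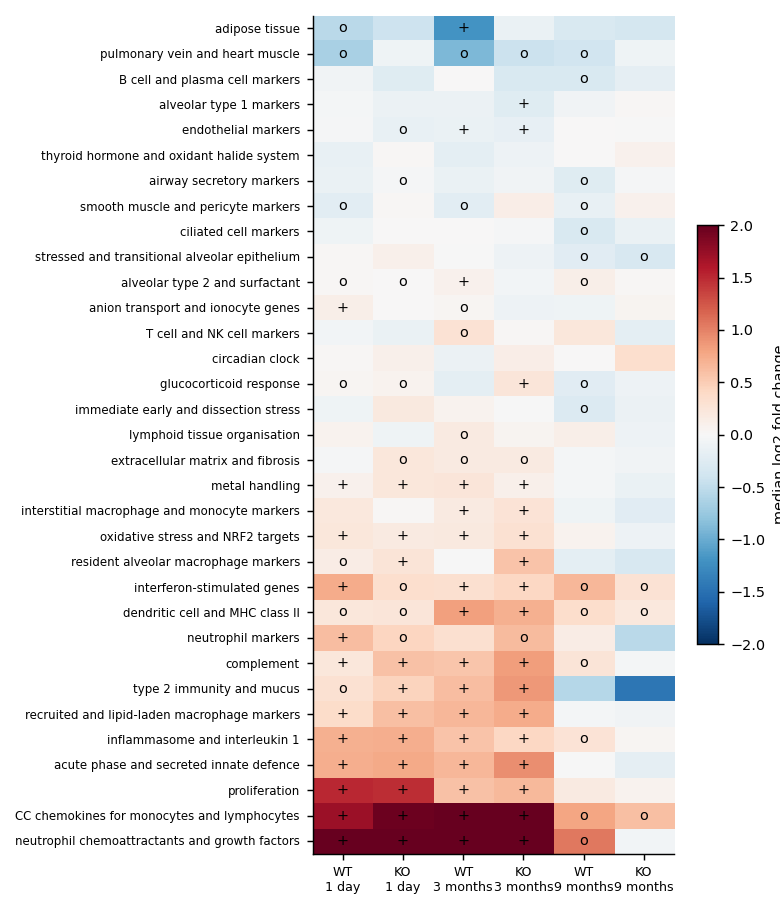
Median log2 fold change of silica against air for each fixed gene list. A cross marks adjusted p under 0.05 by camera with the preset and with an estimated correlation, and a ring with the preset correlation alone.

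Many inflammatory genes were still raised at 3 months in wildtype silica lungs. Class II genes H2-Ab1 (0.86 ± 0.07), H2-Eb1 (0.81 ± 0.09), Cd74 (0.61 ± 0.07) and H2-Aa (0.59 ± 0.06) rose. The macrophage genes Mmp12 (3.67 ± 0.47), Ctsk (2.67 ± 0.15), Spp1 (1.52 ± 0.17) and Fabp5 (0.84 ± 0.14) rose, Ctsk from 12.2 ± 2.14 to 77.8 ± 11.0 CPM (6 against 6 mice). Chemoattractants Cxcl5 (5.28 ± 0.61), Cxcl3 (4.00 ± 0.67) and Cxcl1 (3.45 ± 0.28) and chemokines Ccl22 (3.19 ± 0.30), Ccl17 (3.17 ± 0.42), Ccl3 (2.72 ± 0.37) and Ccl6 (1.59 ± 0.10) rose. Saa3 (3.41 ± 0.43) and Lcn2 (2.72 ± 0.14) remained above air, at 17.9 ± 13.6 against 1.47 ± 1.23 CPM and 363 ± 46.2 against 55.1 ± 6.44 CPM.

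Further wildtype increases at 3 months were the regulatory T cell receptor Ctla4 (2.11 ± 0.37), the alarmin receptor Il1rl1 (1.42 ± 0.20), the monocyte receptors Ccr2 (0.87 ± 0.15) and Cx3cr1 (0.76 ± 0.22), complement C3 (0.94 ± 0.09), Cfb (1.45 ± 0.16) and C1qa (0.90 ± 0.18) and Il1rn (1.75 ± 0.17) and Il1b (1.16 ± 0.26). Also higher were the protease inhibitor Timp1 (2.36 ± 0.39), Col3a1 (0.42 ± 0.09), Slc7a11 (2.55 ± 0.30), Steap4 (1.90 ± 0.15) and Pigr (2.17 ± 0.23). The lectin Asgr2 (3.15 ± 0.45) and Ly6i (4.84 ± 0.52) rose. Resident alveolar macrophage markers split, since Marco (1.51 ± 0.16) and Plet1 (0.76 ± 0.12) rose while Siglecf (-1.48 ± 0.24) and Ear1 (-1.21 ± 0.25) fell. Falls also took in the fat droplet gene Cidec (-1.79 ± 0.33), the heart muscle genes Mybphl (-1.74 ± 0.41), Sln (-1.51 ± 0.42), Myl4 (-1.14 ± 0.32) and Actc1 (-0.76 ± 0.22), Cpne5 (-1.60 ± 0.34) and the capillary gene Gpihbp1 (-0.46 ± 0.10).

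At 3 months in wildtype mice 374 of 12647 tested genes passed adjusted p under 0.05 in edgeR, 283 higher and 91 lower, and 102 changed at least 2-fold. With voom quality weights the count was 573, with all 70 libraries 190 and without KO_silica_3m replicate 3, which shares the model, 575. Of 33 lists 22 passed, and 16 of these with an estimated correlation. Of 9 acute phase genes at 3 months 5 rose and 4 did not pass (7 higher over the list alone, median 0.66, adjusted p = 6.88e-21, adjusted p = 1.07e-06 with an estimated correlation). Of 5 neutrophil chemoattractants at 3 months 3 rose and 2 did not pass (5 higher over the list alone, median 3.45, adjusted p = 8.11e-17, adjusted p = 2.86e-05 with an estimated correlation). Of 6 CC chemokines at 3 months 5 rose and 1 did not pass (5 higher over the list alone, median 2.15, adjusted p = 7.48e-33, adjusted p = 3.82e-08 with an estimated correlation). Of 11 dendritic cell and class II genes at 3 months 9 rose and 2 did not pass (9 higher over the list alone, median 0.81, adjusted p = 7.48e-33, adjusted p = 2.86e-05 with an estimated correlation). Of 14 recruited macrophage markers at 3 months 8 rose and 6 did not pass (10 higher over the list alone, median 0.66, adjusted p = 6.57e-25, adjusted p = 3.14e-04 with an estimated correlation). Of 12 complement genes at 3 months 6 rose and 6 did not pass (9 higher over the list alone, median 0.56, adjusted p = 8.11e-17, adjusted p = 2.76e-05 with an estimated correlation). Of 8 proliferation genes at 3 months 2 rose and 6 did not pass (4 higher over the list alone, median 0.59, adjusted p = 2.36e-07, adjusted p = 0.00308 with an estimated correlation). Of 10 inflammasome genes at 3 months 2 rose, 1 fell and 7 did not pass (4 higher and 1 lower over the list alone, median 0.57, adjusted p = 2.71e-06, adjusted p = 0.00949 with an estimated correlation). Of 10 interstitial macrophage and monocyte markers at 3 months 4 rose and 6 did not pass (5 higher and 1 lower over the list alone, median 0.17, adjusted p = 3.78e-04, adjusted p = 0.0318 with an estimated correlation). Of 17 oxidative stress genes at 3 months 5 rose and 12 did not pass (9 higher over the list alone, median 0.20, adjusted p = 2.63e-08, adjusted p = 0.00335 with an estimated correlation). Of 10 heart muscle genes at 3 months 3 fell and 7 did not pass (10 lower over the list alone, median -0.90, adjusted p = 2.63e-08, adjusted p = 0.0962 with an estimated correlation).

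Knockout lungs at 3 months raised macrophage, acute phase, chemokine and class II genes. Macrophage genes Mmp12 (4.43 ± 0.51), Ctsk (2.66 ± 0.16), Spp1 (1.83 ± 0.18), Gpnmb (1.82 ± 0.23) and Marco (1.99 ± 0.16) rose, Ctsk from 12.4 ± 1.68 to 78.3 ± 19.6 CPM (6 against 6 mice). Part of this came from KO_silica_3m replicate 3, with an Mmp12 of 185.9 (others 24.8 to 47.0) CPM and a Gpnmb of 267.4 (others 77.2 to 101.0) CPM. Without it Mmp12 gave 3.62 and Gpnmb 1.38. Saa3 (4.74 ± 0.49) and Lcn2 (2.70 ± 0.15) rose, as did the chemoattractants Cxcl3 (4.80 ± 0.70), Cxcl5 (4.15 ± 0.66), Cxcl1 (2.62 ± 0.30) and Csf2 (1.42 ± 0.39) and the chemokines Ccl17 (3.64 ± 0.53), Ccl22 (3.55 ± 0.36), Ccl6 (1.77 ± 0.10) and Ccl9 (1.19 ± 0.17). Class II and dendritic cell genes H2-Ab1 (0.70 ± 0.07), H2-Eb1 (0.74 ± 0.09), H2-Aa (0.41 ± 0.06) and Itgae (1.59 ± 0.18) rose. Alveolar type 1 cell genes Akap5 (-0.46 ± 0.07), Hopx (-0.43 ± 0.10), Emp2 (-0.31 ± 0.07) and Clic5 (-0.28 ± 0.08) and the endothelial receptor Kdr (-0.40 ± 0.06) fell.

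Among other knockout increases at 3 months were complement C1qa (1.31 ± 0.19), C1qb (1.31 ± 0.21), Cfb (1.32 ± 0.16) and C3 (1.00 ± 0.09), Il1rn (2.08 ± 0.18), Chil1 (2.74 ± 0.14), Wfdc17 (3.55 ± 0.45) and Ly6i (5.31 ± 0.63). Lymphoid genes were the plasma cell gene Jchain (1.8 ± 0.50), the B cell chemoattractant Cxcl13 (1.47 ± 0.38) and Ctla4 (1.45 ± 0.36). Matrix, metal and carrier genes were Timp1 (1.35 ± 0.34) and Tnc (0.83 ± 0.22), Steap4 (1.96 ± 0.16) and Ftl1 (0.47 ± 0.11), Slc7a11 (2.13 ± 0.29) and Pigr (2.20 ± 0.23). The largest falls were in the brain-type proteoglycan Bcan (-2.08 ± 0.26), the adhesion gene Cadm2 (-1.47 ± 0.31), the xenobiotic enzyme Cyp1a1 (-1.36 ± 0.38), the esterase Ces1f (-1.32 ± 0.29) and Cpne5 (-1.26 ± 0.33). Siglecf (-1.10 ± 0.24) fell as it did in wildtype mice.

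In knockout mice at 3 months 607 of 12647 tested genes passed adjusted p under 0.05 in edgeR, 382 higher and 225 lower, with 123 changed at least 2-fold. With all 70 libraries the count was 306, with the compared groups only 319, and it was 472 without KO_silica_3m replicate 3 and 431 to 625 without any other single library. Of 33 lists 20 passed, and 17 of these with an estimated correlation. Of 9 knockout acute phase genes at 3 months 7 rose and 2 did not pass (9 higher over the list alone, median 0.93, adjusted p = 3.67e-31, adjusted p = 9.50e-09 with an estimated correlation). Of 5 knockout neutrophil chemoattractants at 3 months 4 rose and 1 did not pass (4 higher and 1 lower over the list alone, median 2.62, adjusted p = 1.88e-08, adjusted p = 0.00115 with an estimated correlation). Of 6 knockout CC chemokines at 3 months 5 rose and 1 did not pass (5 higher over the list alone, median 2.15, adjusted p = 4.83e-27, adjusted p = 6.63e-08 with an estimated correlation). Of 11 knockout dendritic cell and class II genes at 3 months 10 rose and 1 did not pass (10 higher over the list alone, median 0.70, adjusted p = 2.42e-24, adjusted p = 3.20e-04 with an estimated correlation). Of 14 knockout recruited macrophage markers at 3 months 10 rose and 4 did not pass (12 higher and 1 lower over the list alone, median 0.75, adjusted p = 4.83e-27, adjusted p = 3.20e-04 with an estimated correlation). Of 12 knockout complement genes at 3 months 10 rose and 2 did not pass (11 higher over the list alone, median 0.83, adjusted p = 8.26e-24, adjusted p = 1.43e-06 with an estimated correlation). Of 8 knockout proliferation genes at 3 months 2 rose and 6 did not pass (4 higher over the list alone, median 0.64, adjusted p = 8.64e-06, adjusted p = 0.00824 with an estimated correlation). Of 10 knockout inflammasome genes at 3 months 3 rose and 7 did not pass (4 higher over the list alone, median 0.42, adjusted p = 1.44e-06, adjusted p = 0.00824 with an estimated correlation). Of 10 knockout interstitial macrophage and monocyte markers at 3 months 3 rose and 7 did not pass (3 higher over the list alone, median 0.27, adjusted p = 6.64e-05, adjusted p = 0.0172 with an estimated correlation). Of 17 knockout oxidative stress genes at 3 months 5 rose and 12 did not pass (7 higher over the list alone, median 0.30, adjusted p = 1.41e-04, adjusted p = 0.0346 with an estimated correlation). Of 10 knockout alveolar type 1 markers at 3 months 5 fell and 5 did not pass (5 lower over the list alone, median -0.24, adjusted p = 2.64e-07, adjusted p = 0.0346 with an estimated correlation). Of 11 knockout glucocorticoid response genes at 3 months 1 rose and 10 did not pass (3 higher over the list alone, median 0.24, adjusted p = 2.42e-07, adjusted p = 0.0434 with an estimated correlation). KO_silica_3m replicate 3 stood apart, since its chi-square against each other mouse of its group was 6.14 to 9.24 per degree of freedom, against 1.62 to 3.23 between the others, and its voom quality weight was 0.280. It held less of the secretory, ciliated and heart muscle genes Scgb1a1, 3900.9 (others 7870.0 to 9619.9), Foxj1, 28.7 (others 54.0 to 73.9), and Myh6, 12.3 (others 174.7 to 417.3), in CPM. Without it the alveolar type 1 list had a median of -0.19 (adjusted p = 7.93e-06 with the preset correlation).

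With all mice few genes passed at 9 months. In wildtype lungs Ly6i (3.02 ± 0.45, adjusted p = 0.00237), Vnn1 (1.38 ± 0.18, adjusted p = 3.63e-04) and Slc39a8 (0.51 ± 0.09, adjusted p = 0.0189) rose, Vnn1 (an epithelial pantetheinase) from 17.3 ± 6.49 to 45.6 ± 6.27 CPM (5 against 5 mice). In knockout lungs Ly6i (3.31 ± 0.40), Slc13a3 (2.66 ± 0.32), Asgr2 (2.59 ± 0.52), Ccl22 (2.25 ± 0.48), Cd207 (2.0 ± 0.42), Vnn1 (1.76 ± 0.16), Vnn3 (1.35 ± 0.19), Nnat (1.11 ± 0.20), Noxa1 (1.06 ± 0.22) and Tlr11 (1.00 ± 0.21) rose and Cpne5 (-1.41 ± 0.25), Nfil3 (-0.98 ± 0.20), Adssl1 (-0.83 ± 0.17), Scd1 (-0.80 ± 0.15), Rps21 (-0.59 ± 0.13) and Krt18 (-0.51 ± 0.10) fell. Vnn1 went from 13.6 ± 3.04 to 46.7 ± 5.32 CPM (6 against 6 mice). Slc26a4 itself did not pass in wildtype (1.03 ± 0.55, adjusted p = 0.763) or knockout mice (-0.12 ± 0.64, adjusted p = 0.977). Without 3 air mice of 9 months (WT_air_9m replicate 5, KO_air_9m replicates 4 and 5) the knockout value was 2.16 (adjusted p = 0.00517).

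Air mice of 9 months differed widely from each other. Chil3, a chitinase-like protein of alternatively activated macrophages, ranged from 673 to 8010 CPM over the 11 air mice and from 630 to 2470 over the 11 silica mice. Lcn2 ranged from 56.2 to 498 CPM in air and from 279 to 535 after silica. The values of Ctsk were 85.0 ± 132 (wildtype air, 5 mice), 137 ± 27.8 (wildtype silica, 5), 92.9 ± 102 (knockout air, 6) and 123 ± 34.8 (knockout silica, 6). At 1 day and 3 months no group SD of Ctsk was above 19.6 CPM.

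**Figure D3:**
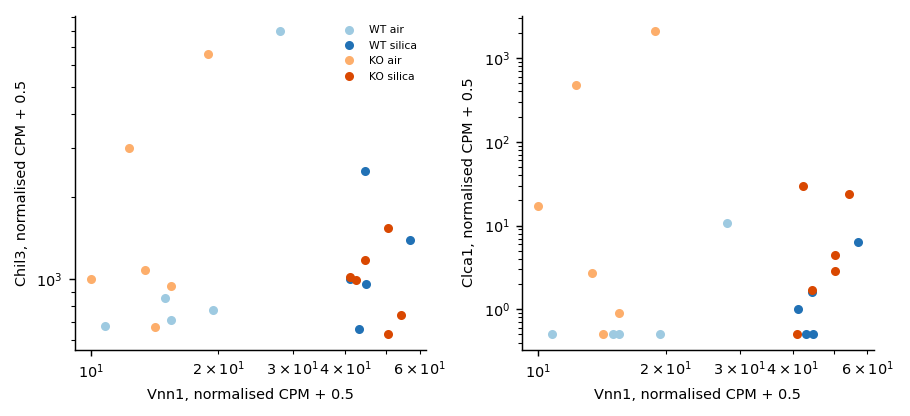
Chil3 and Clca1 against Vnn1 in the 22 mice of 9 months, in normalised CPM plus 0.5.

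At 9 months in wildtype mice 3 of 12826 tested genes passed adjusted p under 0.05 in edgeR, 3 higher and 0 lower (875 at unadjusted p under 0.05). In knockout mice 23 of 12826 tested genes passed adjusted p under 0.05 in edgeR, 16 higher and 7 lower (1350 at unadjusted p under 0.05). DESeq2 called 3 and 50, voom with quality weights 42 and 143, edgeR with 1 surrogate variable 41 and 200, with all 70 libraries 9 and 147, with the compared groups only 2 and 14, and without the 3 air mice named above 211 and 218. Of 33 lists 15 passed in wildtype and 4 in knockout mice with the preset correlation, and 0 of either by camera with an estimated correlation. Of 11 wildtype dendritic cell and class II genes at 9 months 11 did not pass (0 over the list alone, median 0.35, adjusted p = 1.48e-06, adjusted p = 0.177 with an estimated correlation). Of 17 wildtype interferon-stimulated genes 17 did not pass (1 higher over the list alone, median 0.66, adjusted p = 1.48e-06, adjusted p = 0.307 with an estimated correlation). Of 7 wildtype CC chemokines 7 did not pass (1 higher over the list alone, median 0.80, adjusted p = 3.53e-05, adjusted p = 0.177 with an estimated correlation). Of 11 knockout dendritic cell and class II genes 11 did not pass (3 higher over the list alone, median 0.22, adjusted p = 3.22e-05, adjusted p = 0.384 with an estimated correlation). Of 17 knockout interferon-stimulated genes 17 did not pass (0 over the list alone, median 0.28, adjusted p = 4.20e-04, adjusted p = 0.872 with an estimated correlation). Of 7 knockout CC chemokines 1 rose and 6 did not pass (1 higher over the list alone, median 0.59, adjusted p = 9.80e-04, adjusted p = 0.652 with an estimated correlation). Without WT_air_9m replicate 5 the wildtype count was 20, and without KO_air_9m replicate 4 the knockout count was 63.

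The log2 fold changes of silica in wildtype and knockout lungs resembled each other at 1 day and 3 months. With all mice in they did so less at 9 months, and r without the 3 air mice named above was not computed. At 1 day Pearson r was 0.575 (jackknife standard error 0.099) and Spearman rho 0.262 over 12558 tested genes, and r was 0.898 over the 384 genes called in either genotype. At 3 months Pearson r was 0.584 (0.06) and Spearman rho 0.295 over 12647 tested genes, and r was 0.859 over the 769 called in either. At 9 months Pearson r was 0.188 (0.131) and Spearman rho 0.079 over 12826 tested genes, and r was 0.947 over the 24 called in either. At 1 day 154 genes were higher in both genotypes, where 4.18 were expected from the counts alone, and 2 lower in both (0.118 expected). At 3 months 193 were higher in both (8.55 expected) and 19 lower in both (1.62 expected), and at 9 months 2 were higher in both (0.00374 expected). No gene was called in opposite directions in edgeR at any of the 3 times. Of the wildtype calls 276 of 298 at 1 day and 348 of 374 at 3 months had the same sign in knockouts. The reverse held for 238 of 242 and 549 of 607. Genes are not independent of each other, so no p was taken across genes.

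**Figure D4:**
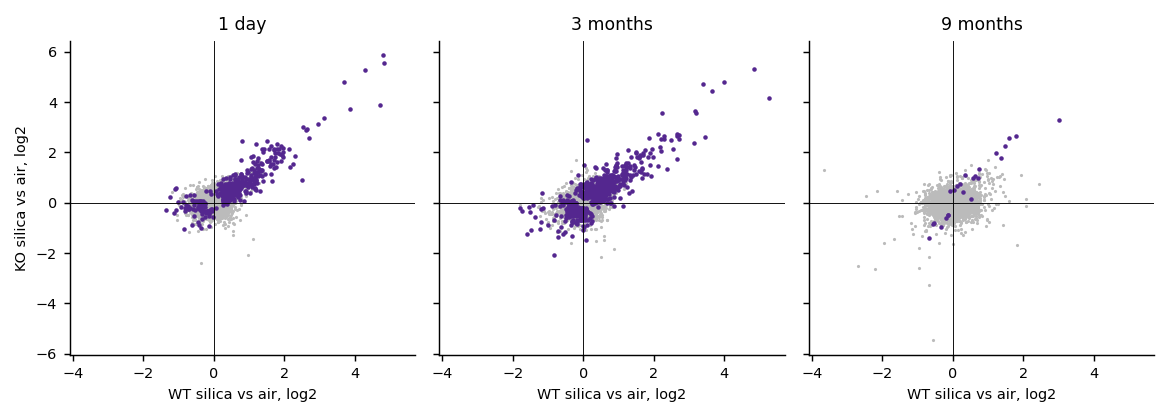
Log2 fold changes of silica against air in wildtype and knockout lungs at each time. Genes at adjusted p under 0.05 in either genotype are purple.

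Tests of a different silica response between genotypes called few genes. In the edgeR fit of each time, and of all times for the mean, the count was 0 at each of the 3 times and 0 for their mean, with 716, 970, 901 and 1317 genes at an unadjusted p under 0.05. DESeq2 called 0, 1, 2 and 11 genes, and voom with quality weights 1, 0, 1 and 55. At 3 months edgeR called 1 gene with size factors, without a low-count filter, with 1 surrogate variable or with all 70 libraries, and 1 gene in 8 of 24 fits without 1 library. The smallest p values belonged to the Wnt regulator Tcf7l1 (1.05 ± 0.22, adjusted p = 0.396), the muscle chaperone Hspb7 (1.65 ± 0.36, adjusted p = 0.396) and the kinase Ak1 (0.88 ± 0.20, adjusted p = 0.396) at 1 day. At 3 months they belonged to the growth factor Ndnf (-0.79 ± 0.14, adjusted p = 0.0533), to Israa (0.71 ± 0.16, adjusted p = 0.342) and to Col3a1 (-0.57 ± 0.13, adjusted p = 0.342). At 9 months they were those of Rab27b (-0.74 ± 0.15, adjusted p = 0.351), Lars2 (1.02 ± 0.21, adjusted p = 0.351) and Fbrs (0.98 ± 0.21, adjusted p = 0.351). Over the 3 times they belonged to the glucose-sensing factor Mlxipl (1.39 ± 0.30), Plin4 (0.89 ± 0.21) and Nova2 (0.77 ± 0.18), each at adjusted p = 0.176. Slc26a4 gave (0.25 ± 0.54, adjusted p = 0.965) at 1 day and (0.37 ± 0.48, adjusted p = 0.905) at 3 months. In simulated counts, with many genes changed, 73.1% of 2-fold differences were recovered at 1 day, 77.6% at 3 months, 61.2% at 9 months and 85.1% for the mean. Few changed genes, or mice standing apart, may lower the share.

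Some lists passed for the interaction with the preset correlation and none of them with an estimated correlation by camera. Of 10 smooth muscle and pericyte markers over the 3 times 10 did not pass (3 higher over the list alone, median 0.26, adjusted p = 5.05e-06, adjusted p = 0.342 with an estimated correlation). Of 20 extracellular matrix genes at 1 day 20 did not pass (0 over the list alone, median 0.23, adjusted p = 1.31e-04, adjusted p = 0.804 with an estimated correlation). Of 10 alveolar type 1 markers at 3 months 10 did not pass (3 lower over the list alone, median -0.19, adjusted p = 4.53e-04, adjusted p = 0.354 with an estimated correlation).

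Within single groups of mice the count of genes that differed by genotype depended on the settings. In air at 1 day the G protein regulator Rgs2 (0.69 ± 0.13) and the cathepsin Ctss (0.49 ± 0.10) were higher in knockouts, and Nes (-0.44 ± 0.08), Banp (-0.64 ± 0.12), Klf4 (-1.04 ± 0.20) and Dusp8 (-0.82 ± 0.16) lower. Slc26a4 there gave (-2.15 ± 0.47, adjusted p = 0.0824). In air at 3 months the glycogen phosphorylase Pygl (0.55 ± 0.09), the ectonucleotidase Nt5e (0.50 ± 0.08), Ndnf (0.60 ± 0.10), Mthfd1 (0.43 ± 0.08), St8sia4 (0.55 ± 0.12), Fyb (0.61 ± 0.13) and Igfbp2 (0.58 ± 0.12) were higher and Slc26a4 (-2.46 ± 0.39), Shank3 (-0.43 ± 0.09), Caskin2 (-0.41 ± 0.08), Sh2d3c (-0.43 ± 0.09), Foxo3 (-0.54 ± 0.11) and Lrrc32 (-0.58 ± 0.12) lower. After silica at 1 day Slc26a4 was the only gene called in the edgeR fit of that time, against 12 genes in DESeq2 and 5 by voom with quality weights (-1.90 ± 0.24). At 3 months after silica Pygl (0.49 ± 0.09), Rrad (1.24 ± 0.25), Clec7a (0.56 ± 0.12) and Hebp1 (0.62 ± 0.14) were higher and Slc26a4 (-2.08 ± 0.23), Lars2 (-0.58 ± 0.10), Dad1 (-0.58 ± 0.10), Muc1 (-0.40 ± 0.07), Pabpc1 (-0.48 ± 0.09) and Cers2 (-0.44 ± 0.09) lower. At 9 months in air Lars2 (-0.88 ± 0.15) and Mir6236 (-1.29 ± 0.22) were lower. The calls numbered 6, 18 and 2 in air and 1, 22 and 0 after silica at the 3 times in order. At an unadjusted p under 0.05 the numbers were 1257, 1370 and 1286 in air and 959, 1297 and 512 after silica. In air DESeq2 called 22 at 1 day and 76 at 3 months, voom with quality weights 181 and 108, and edgeR with the compared groups only 125 and 68. At 9 months in air DESeq2 called 27 and edgeR with all 70 libraries 78, and at 3 months after silica edgeR called 2 with all 70 libraries and 1 with the compared groups only. Without 1 library edgeR called 0 to 71 in air at 1 day and 4 to 113 at 3 months. For the count of 0 DESeq2 called 0 and voom with quality weights 1.

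Over all 6 pairs of groups and 70 mice, these were among the genes with the smallest adjusted p for genotype in each direction. The neutrophil gene S100a9 (0.78 ± 0.14), the monocyte receptor Ccr2 (0.42 ± 0.08), the lymphocyte genes Il18rap (0.43 ± 0.08), Ms4a4c (0.62 ± 0.12), Itga4 (0.26 ± 0.05) and St8sia4 (0.31 ± 0.06) and the interferon-inducible Iigp1 (0.53 ± 0.10) were higher, with Pygl (0.35 ± 0.06) and Rgs2 (0.31 ± 0.06). Lower were Slc26a4 (-1.96 ± 0.21), Npr3 (-0.49 ± 0.09), Dll1 (-0.47 ± 0.08), Cxx1a (-0.38 ± 0.08), Alas1 (-0.26 ± 0.05), Dcaf12 (-0.25 ± 0.05), Dnajb2 (-0.24 ± 0.05), Baiap2 (-0.19 ± 0.04), Csnk1d (-0.18 ± 0.04) and Csnk1e (-0.17 ± 0.03). 435 of 13252 tested genes passed adjusted p under 0.05 in edgeR, 205 higher and 230 lower, and 7 differed at least 2-fold. Without 1 library the count was 303 to 677. With the percent of counts in Lars2 as a covariate, which was 9.22 ± 1.87 in wildtype and 7.41 ± 1.87 in knockout mice, 82 of the 435 still passed.

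With the preset correlation 13 of 33 lists passed for the genotype over all groups, and 0 by camera with an estimated correlation. Of 10 B cell and plasma cell markers 3 rose and 7 did not pass (7 higher over the list alone, median 0.28, adjusted p = 4.00e-05, adjusted p = 0.340 with an estimated correlation). Of 8 neutrophil markers 2 rose and 6 did not pass (5 higher over the list alone, median 0.36, adjusted p = 4.26e-05, adjusted p = 0.311 with an estimated correlation). Of 13 T cell and NK cell markers 1 rose and 12 did not pass (3 higher over the list alone, median 0.32, adjusted p = 5.95e-04, adjusted p = 0.311 with an estimated correlation). Of 15 immediate early genes 3 fell and 12 did not pass (5 lower over the list alone, median -0.17, adjusted p = 2.61e-04, adjusted p = 0.344 with an estimated correlation). Of 12 glucocorticoid response genes 2 fell and 10 did not pass (6 lower over the list alone, median -0.15, adjusted p = 0.00125, adjusted p = 0.341 with an estimated correlation). Fewer than 3 members of the red blood cell, skeletal muscle and thymus lists were tested, so those lists were not.

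Genes near Slc26a4 were called more often for genotype than others. Within 10 Mb 6 of 57 tested genes passed (10.5%), against 429 of 13184 elsewhere (3.25%). The odds ratio was 3.50 (95% range 1.22 to 8.21, Fisher exact p = 0.0107). Besides Slc26a4 the near genes were Ankmy2 (0.21 ± 0.06), Bcap29 (0.23 ± 0.07), Pik3cg (0.19 ± 0.05), Rsad2 (-0.80 ± 0.23) and Tmem18 (0.17 ± 0.05), on chromosome 12 between 26442743 and 36197291. Leaving Slc26a4 itself out gave an odds ratio of 2.91 (Fisher exact p = 0.0360), and within 20 Mb 2.23 (Fisher exact p = 0.0629).

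Differences between times in the silica effect, averaged over genotypes, were tested as silica minus air. From 1 day to 3 months the dendritic cell integrin Itgae (0.96 ± 0.20), the actin bundler Fscn1 (1.43 ± 0.32), the antigen presentation gene Wdfy4 (0.66 ± 0.13) and Naaa (0.55 ± 0.11) and Adam23 (0.93 ± 0.21) gained and the prostaglandin synthase Ptgs2 (-0.89 ± 0.19), Pcsk6 (-0.85 ± 0.17) and Bcan (-1.24 ± 0.28) lost. From 3 to 9 months Cd177 (-2.97 ± 0.50), Ch25h (-2.15 ± 0.37), Ctsk (-2.12 ± 0.42), Ccl6 (-1.17 ± 0.24), Mmp12 (-3.07 ± 0.64), Dcstamp (-2.46 ± 0.53), Gpnmb (-1.64 ± 0.35) and Nek2 (-1.39 ± 0.29) lost, as did Slc26a4 (-2.02 ± 0.50), while Nfib (0.30 ± 0.06), Nfia (0.37 ± 0.09), Gja6 (1.44 ± 0.31), Dach1 (0.51 ± 0.12) and Bmpr2 (0.41 ± 0.10) gained. From 1 day to 9 months Saa3 (-5.26 ± 0.89), Cxcl1 (-3.64 ± 0.56), Lcn2 (-1.94 ± 0.32), Top2a (-1.68 ± 0.29), Nek2 (-1.86 ± 0.30), F10 (-1.48 ± 0.25), Cp (-0.73 ± 0.12), Hp (-0.68 ± 0.09) and Icam1 (-0.48 ± 0.08) and Slc26a4 (-2.29 ± 0.52) lost and Ppp1r13b (0.42 ± 0.08), Slc26a9 (0.61 ± 0.14) and Tlr11 (0.99 ± 0.25) gained. In edgeR 10 genes passed for 3 months minus 1 day (6 higher, 4 lower), 97 for 9 minus 3 months (17 higher, 80 lower) and 115 for 9 months minus 1 day (9 higher, 106 lower). Without WT_air_9m replicate 5 the count for 9 minus 3 months was 2, and for 9 months minus 1 day 73. Without 3 air mice of 9 months (WT_air_9m replicate 5, KO_air_9m replicates 4 and 5) edgeR called 0 genes for 9 minus 3 months (925 at an unadjusted p under 0.05) and 37 for 9 months minus 1 day. With all mice DESeq2 called 116 and 135 and voom with quality weights 0 and 52.

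List differences between times, with all mice, were these. Of 11 dendritic cell and class II genes from 1 day to 3 months 1 rose and 10 did not pass (8 higher over the list alone, median 0.47, adjusted p = 5.92e-14, adjusted p = 0.00293 with an estimated correlation). Of 13 proliferation genes from 1 day to 9 months 6 fell and 7 did not pass (13 lower over the list alone, median -1.43, adjusted p = 1.68e-18, adjusted p = 0.00236 with an estimated correlation). Of 10 acute phase genes from 1 day to 9 months 5 fell and 5 did not pass (8 lower over the list alone, median -0.72, adjusted p = 2.36e-18, adjusted p = 0.00236 with an estimated correlation). Of 6 neutrophil chemoattractants from 1 day to 9 months 4 fell and 2 did not pass (4 lower over the list alone, median -3.41, adjusted p = 2.89e-08, adjusted p = 0.0162 with an estimated correlation). Of 10 stressed alveolar epithelium genes from 1 day to 9 months 2 fell and 8 did not pass (7 lower over the list alone, median -0.36, adjusted p = 8.82e-06, adjusted p = 0.0134 with an estimated correlation). Of 9 metal handling genes from 1 day to 9 months 1 fell and 8 did not pass (4 lower over the list alone, median -0.43, adjusted p = 1.78e-04, adjusted p = 0.0484 with an estimated correlation). Of 14 recruited macrophage markers from 3 to 9 months 4 fell and 10 did not pass (1 higher and 13 lower over the list alone, median -0.73, adjusted p = 1.93e-09, adjusted p = 0.0728 with an estimated correlation).

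Positions of genes named most often in mm10 (GRCm38) were Saa3 chromosome 7, 46711998 to 46719615, Lcn2 chromosome 2, 32384637 to 32387739, Cxcl1 chromosome 5, 90891245 to 90893121, Cxcl3 chromosome 5, 90786101 to 90788093, Cxcl5 chromosome 5, 90759298 to 90761625, Ccl22 chromosome 8, 94745684 to 94751388, Ly6i chromosome 15, 74979534 to 74983434.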

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

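The largest pattern lay in 3 air mice of 9 months, whose Chil3 and Retnla stood above those of the other air mice. In the next the reads of Slc26a4 in the knockout rose with silica. The third was the set of genes that differed by genotype over all groups. The tests of explanations for these 3 patterns, the choice of patterns, the genes screened for single mice and the other splits were run after the results were seen, while the rule for single mice and the tests of time differences were fixed before.

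A mouse was singled out when its gap to the nearest mouse of its group was more than 71.0% of the group's range with 5 mice, or 62.5% with 6. Chance singles out about 1 in 20 groups, or 5.4 of the 108 screened, and 22 were. For total counts these were WT_air_3m replicate 2 (5600000, next 3180000) and KO_silica_3m replicate 2 (868000, next 2070000). For the percent of counts in Lars2 it was KO_silica_1d replicate 3 (1.74, next 6.79). In CPM, for Slc26a4 they were WT_air_9m replicate 5 (74.2, next 21.6) and KO_air_9m replicate 4 (51.7, next 16.8), for Lcn2 WT_air_3m replicate 4 (42.7, next 55.1), WT_air_9m replicate 5 (477, next 82.1) and KO_air_9m replicate 4 (498, next 151), and for Saa3 WT_silica_3m replicate 6 (44.1, next 18.4), WT_air_9m replicate 5 (14.5, next 3.79) and KO_air_9m replicate 4 (241, next 54.0). For Ctsk they were KO_silica_1d replicate 4 (43.4, next 32.8), WT_air_3m replicate 1 (8.06, next 12.3), WT_air_9m replicate 5 (320, next 29.8), WT_silica_9m replicate 5 (186, next 133) and KO_air_9m replicate 4 (294, next 104), and for Mki67 WT_air_9m replicate 5 (101, next 37.0) and KO_air_9m replicate 4 (134, next 41.9). For Vnn1 they were WT_air_3m replicate 4 (2.14, next 10.0) and WT_silica_9m replicate 3 (56.5, next 44.3), and for Chil3 KO_silica_3m replicate 3 (1410, next 701) and WT_air_9m replicate 5 (8010, next 853). WT_air_9m replicate 5 and KO_air_9m replicate 4 made up 11 of the 22.

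Tests of the difference in silica effect between times gave 10 genes for 3 months minus 1 day, 97 for 9 months minus 3 months and 115 for 9 months minus 1 day in edgeR. Without the 3 air mice described next they gave 17, 0 (925 at an unadjusted p under 0.05) and 37, with voom quality weights and all mice 18, 0 and 52, and in DESeq2 with all mice 12, 116 and 135. Lists that differed also with an estimated correlation, as median log2 differences, were dendritic cell and MHC class II, 3 months minus 1 day (0.47), acute phase and secreted innate defence, 9 months minus 1 day (-0.72), neutrophil chemoattractants and growth factors, 9 months minus 1 day (-3.41), metal handling, 9 months minus 1 day (-0.43), stressed and transitional alveolar epithelium, 9 months minus 1 day (-0.36) and proliferation, 9 months minus 1 day (-1.43). These list tests used all air mice of 9 months.

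In WT_air_9m replicate 5 and KO_air_9m replicates 4 and 5, in that order, Chil3 was 8011.1, 6583 and 2996.5 CPM, Clca1 10.3, 2124.4 and 478.6, Retnla 567.6, 3598.8 and 847.3 and Gpnmb 722.5, 528.6 and 173.5. A silica lung with a wrong label cannot be told apart from an air lung here, although 49, 94 and 31 genes lay more than 2-fold above every silica mouse of 9 months, against up to 33 in a silica mouse. Of 319 genes higher in silica than in the 8 other air mice, 93.7, 91.5 and 71.2% in the 3 reached the lowest silica mouse, against 75.1 to 95.1% in silica mice left out of the choice of genes, though Vnn1, Slc13a3 and Ly6i lay below all 11 silica mice in the 3. A piece of lung richer in airway was argued against, because 22 ciliated and secretory markers had a median log2 difference of 0.051 (SD 0.929 between markers) from the other air mice, against a smallest difference of 1.86 for Chil3. The highest Chil3 in the 24 air mice of 1 day and 3 months was 564 CPM, but any cause confined to the mice of 9 months would give this too, so a lung disease that appears with age cannot be told apart from others, and lung sections were not analysed here.

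The Slc26a4 reads of the knockout rose with silica at 1 day by a log2 fold change of 2.88, from 1.74 to 12.8 CPM. Reads leaking evenly between libraries would give air and silica knockouts the same level, so the rise of 2.88 argues against them, and which libraries shared a lane was not analysed here. Reads shared with a related gene were argued against too, since the largest rise of any other Slc26a gene was 0.458 CPM at 1 day (Slc26a10) and 0.815 CPM at 3 months (Slc26a6), and so was a mislabelled sample at these times, since knockout mice lay below wildtype mice in 5 of 6 pairs of groups, while in air at 9 months KO_air_9m replicate 4 (51.7 CPM) went against its label, which stays open. A targeted allele that is still transcribed and induced goes with an interaction of 0.25 at 1 day (95% range -0.80 to 1.30) and 0.37 at 3 months (-0.57 to 1.32), which leave no room for a knockout response below 50% of the wildtype fold. That is a hypothesis, whose bound was set after a first bound (a range that holds 0) that was met as well, and reads across the targeted exons were not analysed here.

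Of the 435 genotype calls 1.38% lay within 10 Mb of Slc26a4, where calls were denser. Only 57 genes were tested there, so linked variants as the main source stay open. Less blood in the knockout lungs stays open, since 8 neutrophil markers had a median log2 difference of 0.363 (0.05 to 0.78) and the erythroid Alas2 fell, but the neutrophil list gave adjusted p = 0.311 with an estimated correlation. The share of counts taken by Lars2, 9.22 ± 1.87% in wildtype and 7.41 ± 1.87% in knockout libraries, cannot be told apart from genotype. With it as a covariate 82 of the 435 still passed, all 435 kept their direction, and their median absolute log2 difference went from 0.226 (standard error 0.057) to 0.173 (0.063), so the calls ended through a smaller difference and a larger error together. Colony or litter differences between the genotypes stay open, as untested.

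Other splits of the same mice were drawn, 100 for each comparison within a time and 60 for each over all times, the real one included. No other split gave as many for these (real count, highest other, splits with as many): WT silica vs air, 1 day (298, 138, 1 of 100), KO silica vs air, 1 day (242, 88, 1 of 100), WT silica vs air, 3 months (374, 84, 1 of 100), KO silica vs air, 3 months (607, 79, 1 of 100), KO vs WT in air, 3 months (18, 7, 1 of 100), KO vs WT in silica, 3 months (22, 5, 1 of 100), KO silica vs air, 9 months (23, 1, 1 of 100), KO vs WT, mean of 6 pairs of groups (435, 1, 1 of 60), silica effect, 9 months minus 3 months (97, 12, 1 of 60) and silica effect, 9 months minus 1 day (115, 0, 1 of 60). Under 5% of the splits gave as many genes as the real groups also for KO vs WT in air, 1 day (6, 23, 2 of 100), WT silica vs air, 9 months (3, 14, 3 of 100) and silica effect, 3 months minus 1 day (10, 15, 2 of 60), but there another split gave more than the real groups, and of 20 comparisons about 1 would come under 5% by chance. The splits keep the 3 air mice of 9 months in, and those of time differences mix ages. They do not show what these mice or age do to a count, and 97 fell to 0 without the 3.

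Chance was not excluded for KO vs WT in silica, 1 day (1, 32, 11 of 100) and KO vs WT in air, 9 months (2, 736, 8 of 100). Where edgeR called 0 genes each split gives as many, so nothing was tested for genotype by silica interaction, 1 day (0, 2, 100 of 100), genotype by silica interaction, 3 months (0, 1, 100 of 100), genotype by silica interaction, 9 months (0, 19, 100 of 100), KO vs WT in silica, 9 months (0, 0, 100 of 100) and genotype by silica interaction, mean of 3 times (0, 310, 60 of 60). The 736 genes of 1 split of the air mice of 9 months, and the 310 of 1 split over all times, point to a structure among the mice other than genotype.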

How the results depend on the processing

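The alternatives moved many counts of called genes and few directions. Chosen after the results were seen were the setting without 3 air mice of 9 months (WT_air_9m replicate 5, KO_air_9m replicates 4 and 5), the chromosome 12 window, and the reading of a list's direction from its test. By the sign of the median 76 of 18035 list values would have reversed, against 29 by the test. The cause was not tested, except that some settings use fewer libraries. WT silica vs air, 1 day had 298 calls, against 761 with voom quality weights, 641 with compared groups only and 220 to 368 in 6 others. With 1 library out it had 206 (without WT_silica_1d replicate 4) to 528 (without KO_silica_1d replicate 3). KO silica vs air, 1 day had 242 calls, against 122 with compared groups only and 184 to 363 in 7 others. Single libraries left out gave 176 (without KO_silica_1d replicate 1) to 283 (without KO_silica_1d replicate 6). Genotype by silica interaction, 1 day had 0 calls, against 1 with voom quality weights and 0 in 6 others. Its range without 1 library was 0 (without WT_air_1d replicate 1) to 1 (without KO_silica_1d replicate 3). KO vs WT in air, 1 day had 6 calls, against 22 in DESeq2, 12 without a low-count filter, 181 with voom quality weights, 11 with 1 surrogate variable, 2 with all 70 libraries, 125 with compared groups only and 6 in 2 others. Dropping 1 library gave 0 (without WT_air_1d replicate 1) to 71 (without KO_silica_1d replicate 3). KO vs WT in silica, 1 day had 1 calls, against 12 in DESeq2, 5 with voom quality weights, 11 with 1 surrogate variable, 0 with all 70 libraries and 1 in 4 others. With 1 library out it had 1 (without WT_air_1d replicate 1) to 7 (without KO_silica_1d replicate 3). WT silica vs air, 3 months had 374 calls, against 573 with voom quality weights, 190 with all 70 libraries and 365 to 520 in 6 others. Single libraries left out gave 265 (without WT_air_3m replicate 5) to 575 (without KO_silica_3m replicate 3). KO silica vs air, 3 months had 607 calls, against 306 with all 70 libraries, 319 with compared groups only and 539 to 608 in 6 others. Its range without 1 library was 431 (without KO_air_3m replicate 2) to 625 (without KO_silica_3m replicate 1). Genotype by silica interaction, 3 months had 0 calls, against 1 with size factors, 1 in DESeq2, 1 without a low-count filter, 1 with 1 surrogate variable, 1 with all 70 libraries and 0 in 2 others. Dropping 1 library gave 0 (without WT_air_3m replicate 1) to 1 (without WT_air_3m replicate 2). KO vs WT in air, 3 months had 18 calls, against 76 in DESeq2, 52 without a low-count filter, 108 with voom quality weights, 54 with 1 surrogate variable, 3 with all 70 libraries, 68 with compared groups only and 17 to 18 in 2 others. With 1 library out it had 4 (without KO_air_3m replicate 2) to 113 (without KO_silica_3m replicate 3). KO vs WT in silica, 3 months had 22 calls, against 37 in DESeq2, 2 with all 70 libraries, 1 with compared groups only and 18 to 30 in 5 others. Single libraries left out gave 6 (without WT_silica_3m replicate 3) to 36 (without KO_silica_3m replicate 1). WT silica vs air, 9 months had 3 calls, against 42 with voom quality weights, 41 with 1 surrogate variable, 9 with all 70 libraries, 211 without 3 air mice of 9 months and 2 to 3 in 5 others. Its range without 1 library was 2 (without WT_air_9m replicate 1) to 20 (without WT_air_9m replicate 5). KO silica vs air, 9 months had 23 calls, against 50 in DESeq2, 13 with a mean CPM of 1, 143 with voom quality weights, 200 with 1 surrogate variable, 147 with all 70 libraries, 14 with compared groups only, 218 without 3 air mice of 9 months and 24 in 2 others. Dropping 1 library gave 7 (without KO_silica_9m replicate 4) to 63 (without KO_air_9m replicate 4). Genotype by silica interaction, 9 months had 0 calls, against 2 in DESeq2, 1 with voom quality weights, 1 with 1 surrogate variable, 1 without 3 air mice of 9 months and 0 in 4 others. With 1 library out it had 0 (without WT_air_9m replicate 1) to 1 (without KO_silica_9m replicate 2). KO vs WT in air, 9 months had 2 calls, against 27 in DESeq2, 17 with 1 surrogate variable, 78 with all 70 libraries, 0 with compared groups only, 4 without 3 air mice of 9 months and 2 to 3 in 4 others. Single libraries left out gave 0 (without WT_air_9m replicate 1) to 11 (without WT_air_9m replicate 5). KO vs WT in silica, 9 months had 0 calls, against 1 with voom quality weights, 1 with 1 surrogate variable, 1 with all 70 libraries, 1 with compared groups only, 1 without 3 air mice of 9 months and 0 in 4 others, and 0 with each single library left out. Genotype by silica interaction, mean of 3 times had 0 calls, against 11 in DESeq2, 55 with voom quality weights and 0 in 5 others. Dropping 1 library gave 0 (without WT_air_1d replicate 1) to 9 (without KO_silica_1d replicate 3). KO vs WT, mean of 6 pairs of groups had 435 calls, against 366 to 549 in 7 others. With 1 library out it had 303 (without KO_air_1d replicate 1) to 677 (without WT_air_9m replicate 5). Silica effect, 3 months minus 1 day had 10 calls, against 18 with voom quality weights, 17 without 3 air mice of 9 months and 9 to 12 in 5 others. Single libraries left out gave 3 (without KO_air_1d replicate 2) to 11 (without KO_silica_1d replicate 3). Silica effect, 9 months minus 3 months had 97 calls, against 0 with voom quality weights, 5 with 1 surrogate variable, 0 without 3 air mice of 9 months and 85 to 116 in 4 others. Its range without 1 library was 2 (without WT_air_9m replicate 5) to 205 (without KO_air_9m replicate 1). Silica effect, 9 months minus 1 day had 115 calls, against 52 with voom quality weights, 37 without 3 air mice of 9 months and 101 to 135 in 5 others. Dropping 1 library gave 73 (without WT_air_9m replicate 5) to 164 (without KO_air_9m replicate 1). Where 0 genes passed, in edgeR the unadjusted counts under 0.05 were 716, 970 and 901 for the interactions of 1 day, 3 months and 9 months, 1317 for their mean and 512 for the genotypes after silica at 9 months. The correlation of WT and KO silica effects across genes, 1 day was 0.575, against 0.516 with a mean CPM of 1, 0.898 over genes called in either genotype and 0.481 to 0.585 with single libraries left out. The correlation of WT and KO silica effects across genes, 3 months was 0.584, against 0.499 with a mean CPM of 1, 0.859 over genes called in either genotype and 0.548 to 0.594 with single libraries left out. The correlation of WT and KO silica effects across genes, 9 months was 0.188, against 0.172 with a mean CPM of 1, 0.947 over genes called in either genotype and 0.106 to 0.247 with single libraries left out. The odds ratio of genotype calls near Slc26a4 was 3.50 within 10 Mb, 4.64 within 5 Mb, 2.60 within 20 Mb and 1.15 over chromosome 12, where Fisher's p was 0.591. Reversed values, as median log2 fold changes for lists, were as follows. 1 surrogate variable gave -0.0180 (airway secretory markers) and 0.136 (ciliated cell markers) for WT silica vs air, 3 months, 0.240 (pulmonary vein and heart muscle) for KO vs WT in silica, 3 months, 0.120 (acute phase and secreted innate defence) for KO silica vs air, 9 months and -0.257 (resident alveolar macrophage markers), -0.193 (recruited and lipid-laden macrophage markers) and -0.0590 (oxidative stress and NRF2 targets) for KO vs WT in air, 9 months. Voom quality weights gave 0.210 (acute phase and secreted innate defence) and 0.101 (extracellular matrix and fibrosis) for KO silica vs air, 9 months and 0.0420 (inflammasome and interleukin 1) for silica effect, 9 months minus 3 months. Without 3 air mice of 9 months gave 0.184 (resident alveolar macrophage markers), 0.417 (type 2 immunity and mucus) and -0.136 (endothelial markers) for WT silica vs air, 9 months, 2.16 (Slc26a4), 2.55 (Saa3), 0.385 (acute phase and secreted innate defence), 0.547 (type 2 immunity and mucus), 0.114 (oxidative stress and NRF2 targets), 0.196 (extracellular matrix and fibrosis) and 0.0870 (alveolar type 2 and surfactant) for KO silica vs air, 9 months, 0.178 (extracellular matrix and fibrosis) for genotype by silica interaction, 9 months, 0.0290 (inflammasome and interleukin 1) and -0.185 (type 2 immunity and mucus) for silica effect, 9 months minus 3 months and 0.358 (CC chemokines for monocytes and lymphocytes), 0.104 (recruited and lipid-laden macrophage markers) and -0.122 (alveolar type 1 markers) for silica effect, 9 months minus 1 day. With single libraries left out, lists that reversed ran from -0.195 (without KO_silica_3m replicate 6) to 0.331 (without KO_silica_3m replicate 3) for pulmonary vein and heart muscle in KO vs WT in silica, 3 months, -0.364 (without WT_air_9m replicate 3) to 0.187 (without WT_air_9m replicate 5) for resident alveolar macrophage markers in WT silica vs air, 9 months, -0.135 (without WT_air_9m replicate 5) to 0.0480 (without WT_air_9m replicate 2) for endothelial markers in WT silica vs air, 9 months, -0.282 (without KO_air_9m replicate 2) to 0.156 (without KO_air_9m replicate 4) for acute phase and secreted innate defence in KO silica vs air, 9 months and -0.129 (without KO_air_9m replicate 6) to 0.0140 (without KO_air_9m replicate 4) for extracellular matrix and fibrosis in KO silica vs air, 9 months. The cause was not tested. Of the calls among named genes those that no longer passed numbered 0 of 396 with size factors, 20 of 396 in DESeq2, 15 of 396 without a low-count filter, 11 of 396 with a mean CPM of 1, 129 of 325 with all 70 libraries, 51 of 293 with compared groups only, 47 of 396 with voom quality weights, 34 of 396 with 1 surrogate variable and 30 of 91 without 3 air mice of 9 months. Over the single libraries left out it was 1101 of 12719. Of the list calls those lost numbered 0 of 218 with size factors, 14 of 218 in DESeq2, 28 of 218 without a low-count filter, 7 of 218 with a mean CPM of 1, 31 of 156 with all 70 libraries, 9 of 141 with compared groups only, 30 of 218 with voom quality weights, 23 of 218 with 1 surrogate variable, 19 of 90 without 3 air mice of 9 months, 156 of 218 with an estimated correlation and 121 of 218 by fry, and 186 of 3688 over single libraries. No paired analysis was possible because the labels give each mouse its own number and nothing links a mouse of one group to a mouse of another. How depth limits the results was not tested, since no simulation varied it. In simulated counts of the same depth 62.7% of genes raised 1.5-fold and 95.5% raised 2-fold were recovered at 1 day in wildtype mice, against 25.4% and 79.1% at 9 months.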

Other observations

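The tests of this part, the set of 97 genes and the leaving out of 3 air mice were chosen after the results were seen. At 1 day and 3 months 97 genes were higher in both genotypes, and 0 were lower in both at both times in edgeR. As a hypothesis these stay higher at 9 months, in other mice, where 84 of the 97 (86.6%) had a positive log2 fold change in wildtype (median 0.33) and 65 (67.0%) in knockout mice (median 0.14). By camera with an estimated correlation p was 0.0560 and 0.187 with all mice, and an exact permutation test of the mean of the 97, added later, gave p = 0.0476 and 0.0823, which left it undecided. Without 3 air mice of 9 months all 97 were positive in both genotypes (medians 0.82 and 0.67, 68 and 70 past the threshold). The exact permutation test then gave p = 0.00794 and 0.00476, the smallest it can reach with so few mice, but the mice left out were high in the same genes, so these values do not decide it either.

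Without 3 air mice of 9 months 211 genes passed in wildtype (156 higher, 55 lower) and 218 in knockout mice (189 higher, 29 lower), against 3 and 23 with them. These 3 mice were left out because they stood apart, and they were high in many of the genes silica raised, so leaving them out favours positive silica effects and shows only how far the counts depend on them. In this setting Slc26a4 in knockouts had a log2 fold change of 2.16 and Saa3 of 2.55.

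As a hypothesis, the 3 air mice may have had the crystal-forming macrophage pneumonia that has been described in ageing mice of 129 strains, in which the Chil3 protein makes up the crystals. Chil3 was at most 564 CPM in 24 earlier air mice against 2997 to 8011 in the 3, which does not decide it, since any cause confined to the mice of 9 months would give the same. In these 3 mice 92, 92 and 70 of the 97 genes reached the lowest silica mouse, against 10 to 35 in the other 8 air mice. Slc13a3 was 1.4, 0.9 and 0.5 CPM in the 3 and 2.89 to 6.84 in silica mice of 9 months, and Ly6i 8.4, 6.3 and 2.3 against 14.2 to 32.9.

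KO_silica_3m replicate 3 had 1408.6 CPM of Chil3 and 267.4 of Gpnmb, but only 8.4 of Vnn1, 0.8 of Ly6i and 3.4 of Slc26a4. Slc13a3 had no count in it. Its Lcn2 (166.9), Saa3 (19), Ctsk (105.6) and Mmp12 (185.9) lay above every knockout air mouse of 3 months (at most 58.9, 1.3, 14.9 and 5.5), as in other silica mice. Its label was not tested. Without it KO silica vs air, 3 months had 472 calls, against 607 with all.

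Between 1 day and 3 months, which share no mice, 127 genes were higher at both in wildtype (5.05 expected) and 132 in knockout mice (6.12 expected). Pearson r across genes was 0.592 and 0.535.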
